A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

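Total RNA of subcutaneous OVCAR3 tumours taken on day 39 from nude mice was hybridised in a single colour (Cy3) to Agilent arrays. Each tumour extract appears on a human design and on a mouse design, so the 12 arrays comprise 3 control and 3 RNASET2-silenced tumours on each of 2 designs. The array names are shared between designs in the labels, and samples were grouped by the labels alone. The labels name different clones and separate experiments, so the 3 replicates of a group are separate tumours of 3 clones. They disagree on the control, which is parental cells in the growth protocol and empty vector in the sample characteristics; the word control is used here for either.

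Per the file headers, the deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction, and the submitters' processing notes give version 10.5.1.1 of that program. The processed intensity had been background-subtracted and detrended by that program and had not been normalized between arrays. The headers name hg19 for the human design and mm9 for the mouse design, and coordinates are given on those builds. The authors also deposited a table of log2 values for each design, with 21299 human and 23176 mouse probes. Its normalization is not given in the sources used here. Its column medians lay between 8.69 and 8.74 on the human design and between 8.06 and 8.10 on the mouse design, so the scale was taken as log2 intensity equalised between arrays. Which array each column describes was tested against the scanner files, and the columns named for a group followed the scanner files of the opposite group. The scanner files had been set as the source of every main result before the data were examined, and the tables as an alternative.

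Control spots and outlier-flagged spots were left out, replicate spots of a probe were averaged, and log2 of the processed signal minus the 75th percentile of each array gave the normalized value. A probe was kept if it was well above background on at least 3 of the 6 arrays of its design, whatever their group. This kept 25088 human and 25882 mouse probes. A gene was represented by its brightest kept probe, which gave 19911 human and 20109 mouse genes. Gene names came from the array files. On the mouse design they were updated through RefSeq accessions of the GRCm38.p6 gene table: 33064 of 55681 probes carried a RefSeq-style accession, 26413 of these matched, and 3093 symbols changed. No such table was used for the 42405 human probes, whose names are those of the array files and can be old.

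The groups were compared with limma 3.58.1 in R 4.3.3, each design fitted apart, with lmFit, eBayes and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Fold changes are silenced minus control on the log2 scale, and SE is the moderated standard error. Gene lists (30 human and 34 mouse) of tumour programmes, host cell types and matrix were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma camera at its preset correlation of 0.01, and counts of members adjusted over the list alone are given beside those over all genes. Camera with an estimated correlation and fry were run as alternatives. The M1 minus M2 balance, the share of probes well above background and the signal against the E1A spike-in probes were compared with two-sided exact permutation tests, for which 3 against 3 arrays cannot give a p under 0.1. A probe not well above background on any array of a group has only a bound there. For such a probe the fold is given as at least the bright group's mean against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal. No array had saturated spots among the probes.

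The genes named were set by a rule written beforehand. RNASET2 and its mouse orthologue were always named, as were MUC16, EPCAM, VIM and MKI67 on human arrays and Adgre1, Cd68, Nos2, Arg1 and Mrc1 on mouse arrays. Up to 8 genes each way with a curated symbol and no overlap between the groups' replicates were taken by size among passing genes, and the list was filled by smallest unadjusted p, stated as not passing, where fewer than 5 passed. Each list described contributes up to 4 members of smallest unadjusted p. A few members that this rule picked are not given here, and the counts of named genes leave out all but 1 of them.

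The fit was tested on simulated data with the real genes' means and spreads. In the same simulation 67 of 19911 human genes were changed by 1 log2 unit, 67 by 2 and 66 by 4. Of these, 29.9%, 73.1% and 95.5% were recovered, and 7 unchanged genes were called. On the 20109 mouse genes the shares were 19.4%, 76.1% and 97.0%, again with 7 unchanged genes called. With no simulated change, 0 genes and 0 lists were called on either design. The simulated genes varied independently, so the 0 lists called say nothing about lists whose members vary together. The number of arrays limits the precision.

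Alternative values came from normexp background correction with an offset of 50, quantile normalization, the median or the spike-ins in place of the 75th percentile, and the percentile over probes detected on all arrays. Other filters, the mean of a gene's probes and the deposited value table were also tried. The alternative fits used an intensity trend, array weights, the row on the slide as a block, the replicate number as a block, other thresholds, and each array left out in turn. All 6 arrays of a design lay on a single slide, so the slide was no batch. The 3 silenced tumours and control 1 lay in row 1, and controls 2 and 3 in row 2, so the row-blocked fit compares the silenced tumours with control 1 within row 1. Mouse probe sequences were aligned to human probe sequences with BLAST 2.17.0 at a word size of 7 and an expectation limit of 0.001.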

Results

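OVCAR3 is an established human ovarian adenocarcinoma cell line. Control and RNASET2-silenced OVCAR3 cells were grown under the skin of male nude mice, 6 weeks old at the start, and tumours were taken on day 39. The tumours hold human carcinoma cells and mouse host cells, so total RNA was read on a human and on a mouse expression array, with 3 control and 3 silenced tumours on each. The scanner files give every main value here. In the authors' deposited table of log2 values of the same arrays, read by its column names, 89.5% of human and 93.9% of mouse genes differ in the opposite direction. On the human arrays 58.2% ± 1.69 (SD, n = 3) of probes were well above background in control tumours and 59.5% ± 2.76 in silenced tumours, a difference of 1.27 percentage points (exact permutation test, two-sided p = 0.5). On the mouse arrays the shares were 48.8% ± 2.38 and 43.0% ± 1.81, a difference of -5.74 points, and p = 0.1 in the exact permutation test was the smallest p that 3 against 3 can give. The 75th percentile of mouse signal against the spike-in probes was -4.16 ± 0.37 in control and -4.55 ± 0.21 in silenced tumours on the log2 scale (exact permutation p = 0.2), and on human arrays it was -2.55 ± 0.18 and -2.46 ± 0.32 (exact permutation p = 0.8). Control 1 was the only control in the slide row of the silenced tumours. On the mouse arrays its signal was -4.51, against -4.60, -4.32 and -4.72 in silenced 1, 2 and 3. Its share of probes was 46.1%, against 45.0%, 41.5% and 42.7%.

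RNASET2, the secreted T2-family ribonuclease targeted in the study, fell in the silenced tumours. Its brightest probe, A_24_P360269 (NM_003730, chromosome 6, 167343227 to 167344538, minus strand, hg19), stood at 4.74 ± 0.15 (SD, n = 3) in control tumours and 2.33 ± 0.11 in silenced tumours, on the log2 scale relative to the 75th percentile of the array. This was a log2 fold change of -2.41 (SE 0.16, limma adjusted p = 0.0239), or 5.30-fold, with all 3 silenced tumours below all 3 controls. A second probe of the same transcript, A_24_P289471, fell by 3.78 on the log2 scale (SE 0.16, limma adjusted p = 0.000705 over 25088 probes). The probes A_33_P3254121 and A_33_P3251163, annotated to other transcripts of the gene, had log2 fold changes of -0.10 (SE 0.16) and -0.68 (SE 0.30) and did not pass. The call for the gene, made on its brightest probe, was lost on leaving out any single array. The limma adjusted p then lay between 0.0794 and 0.34, and the log2 fold change between -2.47 and -2.32. That call was also lost with median centring (adjusted p = 0.088), spike-in scaling (0.137), no filter (0.106), the mean of probes (0.227) and the replicate number as a block (0.254). The probe A_24_P289471 was not put through these alternatives by itself. With the slide row as a block the adjusted p of RNASET2 on human arrays was 0.0524, and 10 other genes were called lower. The human arrays thus carried the labelled difference in the targeted gene, and the mouse arrays hold no such check. On the mouse arrays Rnaset2a, the mouse orthologue, had a log2 fold change of -0.32 (SE 0.14, adjusted p = 0.295), and no value was obtained for Rnaset2b.

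**Figure D1:**
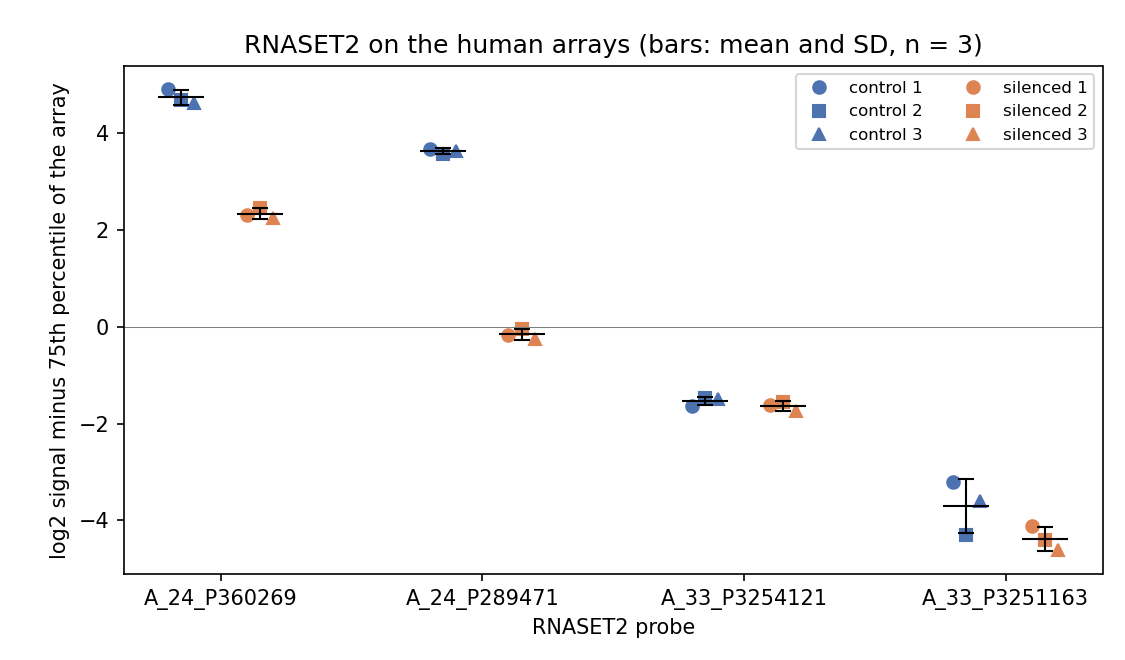
Normalized log2 signal (vertical axis, relative to the 75th percentile of the array) of the 4 RNASET2 probes (horizontal axis) in 3 control and 3 silenced tumours; markers are tumours and bars are mean and SD. The 2 brightest probes differ by -2.41 and -3.78 between the groups, and the 2 dimmer probes by -0.10 and -0.68.

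The first comparison asked which transcripts on the human arrays differed between silenced and control tumours. The RNA also held mouse transcripts, and mouse RNA on human probes is not excluded for the genes and lists below. RNASET2 was the only gene of 19911 to pass on the human arrays, with 0 genes higher and 1 lower, while 1993 genes had an unadjusted p under 0.05, of which 763 were higher and 1230 lower in the silenced tumours. The replicates of the groups did not overlap for 3517 genes, 17.7% of those tested, against 10% expected by chance. That 10% is an average over groupings, and genes vary together, so a single grouping can lie above it by chance. Setting control 1, control 2 and silenced 1 against the others gave 1938 human genes with an unadjusted p under 0.05. The genes of smallest p among those higher in silenced tumours included the retinoid enzymes ALDH1A1 (log2 fold change 2.91, SE 0.39) and DHRS3 (2.56, SE 0.33), each with adjusted p = 0.18. LEMD1, a cancer-testis antigen, was at 2.35 (SE 0.27, adjusted p = 0.18) and DSCAML1, an adhesion molecule, at 1.42 (SE 0.19). The circadian gene PER3 was at 1.20 (SE 0.20, adjusted p = 0.309), and it was well above background on 1 of 3 control arrays. FOXA2, an endodermal transcription factor, was not well above background in any control tumour and at least 4.85-fold higher in silenced tumours (adjusted p = 0.257). On the lower side stood the transcription factors TCF4 (-1.46, SE 0.16) and BHLHE22 (-1.40, SE 0.18), the MHC class II genes HLA-DRB1 (-1.22, SE 0.15) and HLA-DQB1 (-1.18, SE 0.15), and the calcium-binding gene S100A2 (-1.46, SE 0.20), each with adjusted p = 0.18. Probes of the MHC class II genes can share RNA with near-identical copies. GPR18 (-1.63, SE 0.20) and DAPP1 (-2.23, SE 0.29), both expressed in lymphoid cells, were well above background on 3 control arrays and 1 silenced array each. None of these passed. The epithelial marker EPCAM was at -0.40 (SE 0.32, adjusted p = 0.702), the intermediate filament gene VIM at 0.29 (SE 0.19, adjusted p = 0.638) and the proliferation marker MKI67 at 0.08 (SE 0.29, adjusted p = 0.944), which turned to -0.30 with the slide row as a block. The probes of MUC16, which encodes the ovarian tumour antigen CA125, were not well above background on any array.

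Of the 30 gene lists on the human arrays, 10 were called by camera, 6 higher and 4 lower in the silenced tumours. The hypoxia and glycolysis list was higher as a group (median log2 fold change 0.59, camera adjusted p = 1.36e-12), with all 17 measured members above 0. In that list 8 members rose when adjusted over the list alone and 0 over all genes. NDRG1, a stress-responsive gene induced by hypoxia, was at 1.85 (SE 0.31), the pyruvate dehydrogenase kinase PDK1 at 1.15 (SE 0.22), the mitophagy receptor BNIP3 at 0.89 (SE 0.23) and the glycolytic enzyme PGK1 at 0.78 (SE 0.20). With an estimated correlation this list had an adjusted p = 0.384. The cell cycle list was higher (median 0.28, camera adjusted p = 5.04e-06, adjusted p = 0.384 with an estimated correlation), with 22 of 22 members above 0, of which 1, the ribonucleotide reductase subunit RRM2 (1.11, SE 0.19), rose when adjusted over the list alone. The replication gene MCM2 was at 0.57 (SE 0.16) and TOP2A, the replicative topoisomerase, at 0.58 (SE 0.22), while MKI67 was near 0 as given above. Metallothioneins, the metal-binding stress proteins, were higher (median 0.55, camera adjusted p = 0.000254, adjusted p = 0.384 with an estimated correlation). Of 9 measured members 8 lay above 0, and 0 passed when adjusted over the list alone. MT1L was at 0.65 (SE 0.23) and MT1E at 0.55 (SE 0.22), and probes of these near-identical genes can share RNA. These 3 lists were called in the same direction under each alternative fit to the scanner files and with each array left out, and not with an estimated correlation or by fry. No member of a list called on the human arrays passed over all genes.

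The other called lists on the human arrays each lost their call in some alternatives. Oxidative phosphorylation was higher (median 0.17, camera adjusted p = 0.00532, adjusted p = 0.569 with an estimated correlation). Of 22 measured members 21 lay above 0, and 0 passed when adjusted over the list alone. Stress and immediate early genes were higher (median 0.25, camera adjusted p = 0.00998, adjusted p = 0.384 with an estimated correlation), with 13 of 18 members above 0. Over the list alone FOS rose (1.48, SE 0.27), and FOSB stood at 0.74 (SE 0.22) and EGR2 at 0.76 (SE 0.25). Oestrogen response genes were higher (median 0.33, camera adjusted p = 0.0206, adjusted p = 0.384 with an estimated correlation). Of 14 measured members 9 lay above 0, and 3 passed when adjusted over the list alone: CA12, a carbonic anhydrase that hypoxia also induces, at 1.54 (SE 0.35), STC2, a secreted glycoprotein, at 1.24 (SE 0.32) and the trefoil factor TFF3 at 1.27 (SE 0.37). Fibrillar collagen and matrix genes were lower (median -0.65, camera adjusted p = 0.0124, adjusted p = 0.384 with an estimated correlation). Of 15 measured members 10 lay below 0, and 4 passed when adjusted over the list alone: COL1A2 (-1.18, SE 0.21), FN1 (-1.10, SE 0.21), COL1A1 (-0.93, SE 0.22) and ELN (-1.08, SE 0.27). The mesenchymal list was lower (median -0.06, mean -0.36, camera adjusted p = 0.0483, adjusted p = 0.384 with an estimated correlation). Of 16 measured members 10 lay below 0, and 5 passed when adjusted over the list alone, among them N-cadherin CDH2 (-1.36, SE 0.24), FN1, ZEB2 (-0.94, SE 0.19) and TAGLN (-0.98, SE 0.21). Interferon-stimulated genes were lower (median -0.24, camera adjusted p = 0.0177, adjusted p = 0.384 with an estimated correlation). Of 20 measured members 17 lay below 0, and 0 passed when adjusted over the list alone. OAS2 was at -0.87 (SE 0.31) and IFI27 at -0.48 (SE 0.18). Human orthologues of host leukocyte markers were lower (median -0.27, camera adjusted p = 0.035, adjusted p = 0.384 with an estimated correlation). Of 11 measured members 9 lay below 0, and 0 passed when adjusted over the list alone. The MHC class II chaperone CD74 was at -1.12 (SE 0.30) and complement C1QB at -0.81 (SE 0.25). Mouse RNA on these human probes is not excluded. Within row 1 of the slide these 7 lists were not called (adjusted p between 0.12 and 0.396). Without silenced 1 the adjusted p was 0.136 for oxidative phosphorylation, 0.246 for oestrogen response, 0.0923 for collagen, 0.471 for the mesenchymal list and 0.139 for the interferon and leukocyte lists. Without silenced 2 it was 0.112 for the stress list. Without silenced 3 it was 0.0657 for the stress, collagen and leukocyte lists and 0.0724 for the mesenchymal list. Without control 2 it was 0.0611 for the interferon list, and without control 3 it was 0.08 for the leukocyte and mesenchymal lists. Processing ended calls as well. Of 19 alternatives with the preset camera correlation on human arrays, the authors' table with its sign turned among them, the mesenchymal list was called in 8 and the list of host leukocyte orthologues in 9. The mesenchymal and EMT list had an adjusted p of 0.0902 with the percentile over detected probes, 0.0552 with spike-ins, 0.257 with no filter, 0.062 with the mean of probes, 0.0797 with array weights, 0.0646 with the replicate block and 0.0624 in the turned table. For host leukocyte orthologues it was 0.113 with quantile normalization, 0.0503 with the percentile over detected probes, 0.0552 with spike-ins, 0.0766 with the mean of probes, 0.0598 with array weights and 0.103 in the turned table. The interferon-stimulated list had 0.0519 with spike-ins and 0.0554 with array weights, and oestrogen response 0.0723 with median centring and 0.0651 with array weights. Oxidative phosphorylation had 0.141 with quantile normalization and 0.0603 in the turned table, where the stress and immediate early list had 0.0578.

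**Figure D2:**
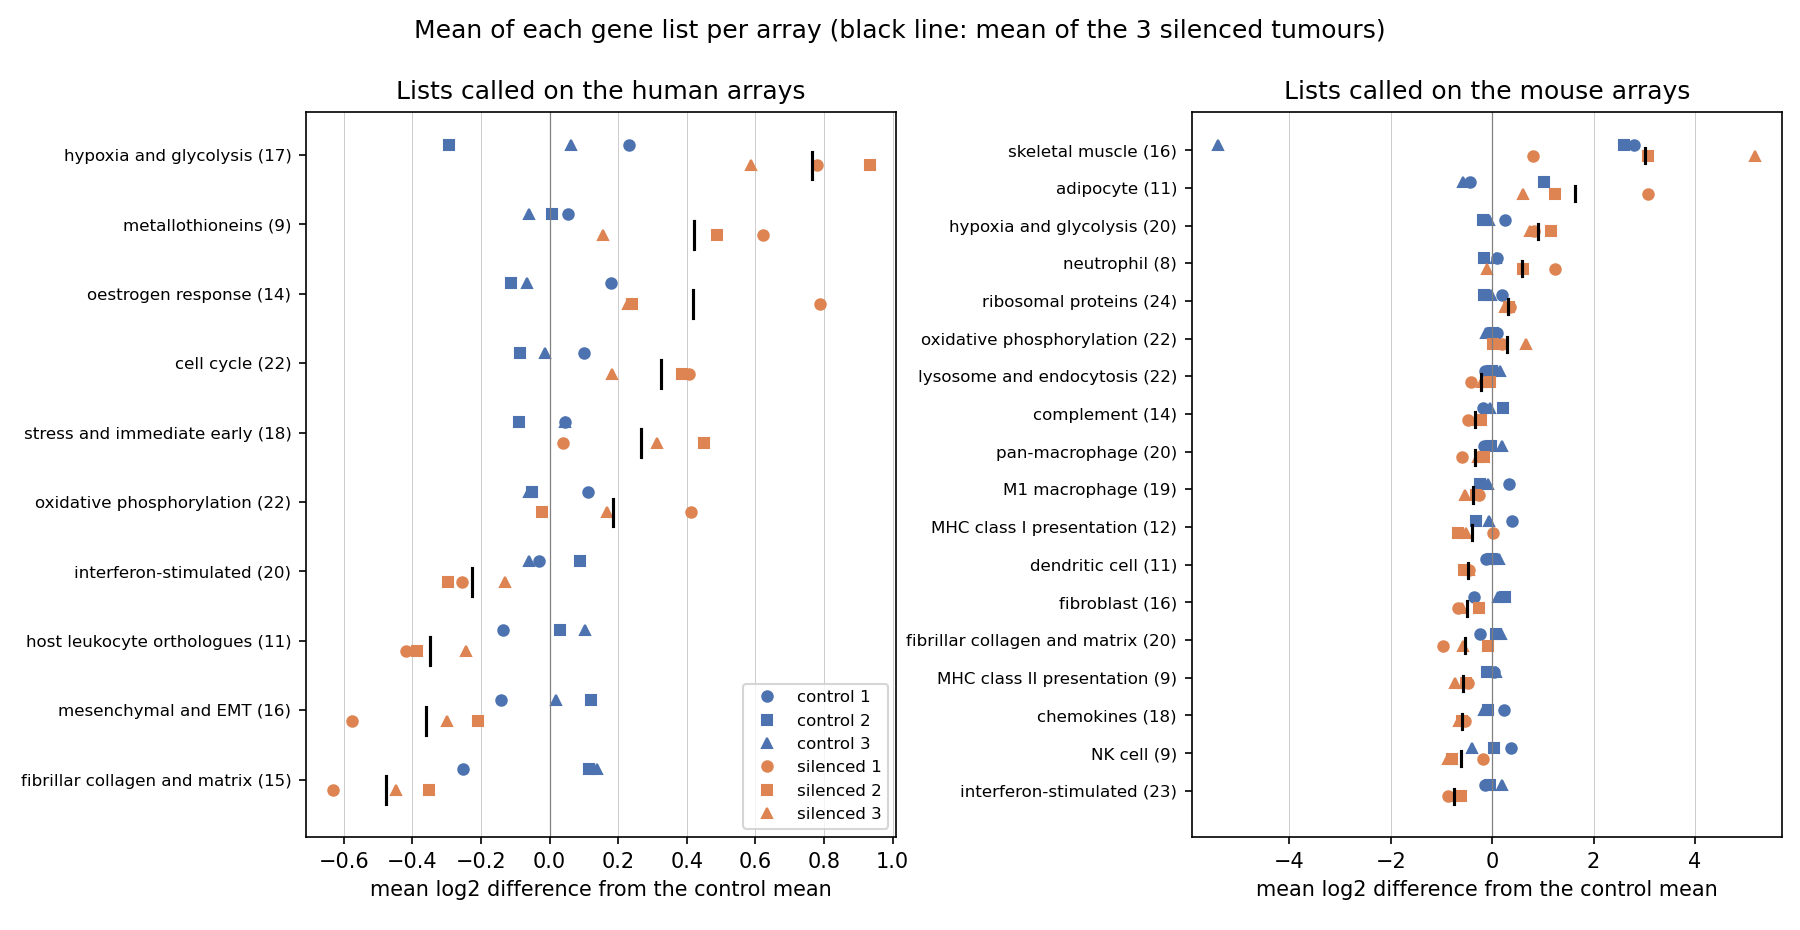
Mean log2 difference from the control mean (horizontal axis) of each list called by camera (vertical axis, number of measured genes in brackets) in each tumour, on human arrays (left) and mouse arrays (right); black lines mark the mean of the 3 silenced tumours. The hypoxia and glycolysis list lies higher in all 3 silenced tumours on both designs (means 0.77 and 0.91), while the skeletal muscle list is spread over a wide range within each group.

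The second comparison asked which transcripts on the mouse arrays differed. The RNA also held human transcripts, and human RNA on mouse probes is not excluded. On the mouse arrays 1 gene of 20109 rose and 1 fell, while 3601 had an unadjusted p under 0.05, 1740 higher and 1861 lower in the silenced tumours. The replicates of the groups did not overlap for 5503 genes, 27.4% of those tested, against 10% expected by chance. A single grouping can lie above that average here too. Setting control 1, silenced 1 and silenced 3 against the others gave 2388 mouse genes with an unadjusted p under 0.05. Foxa2 (NM_010446, chromosome 2, 147868669 to 147868728, minus strand, mm9) rose: it was not well above background in any control tumour and at least 3.73-fold higher in the silenced tumours (limma adjusted p = 0.0427). Its second probe was not well above background on any array. FOXA2 had the same pattern on the human arrays, as given above, so human RNA on the mouse probe is not excluded. The gene that fell, AW555355, was named after its value was seen. It was well above background on all 3 control arrays and on no silenced array (adjusted p = 0.0427), and its bound gives no fold. Both calls were lost on leaving out any single array, with Foxa2 at an adjusted p between 0.147 and 0.534 and AW555355 between 0.209 and 0.613. They were also lost with normexp background correction, where the log2 fold changes of Foxa2 and AW555355 were 0.97 and 0.01. Neither gene was called with no filter, the intensity trend, the slide row block or the replicate block. The filter on all arrays leaves out the probes behind both calls, so it does not test them. In the authors' table with its sign turned Foxa2 stood at 0.67 (adjusted p = 0.154). The higher genes of smallest p that did not pass were the lipoprotein receptor gene Vldlr (1.22, SE 0.19), the transcription factors Klf5 (1.42, SE 0.23) and Rbpj (0.96, SE 0.17), Cracd (1.78, SE 0.29), Fbll1 (1.07, SE 0.17), and Pgk1 (1.11, SE 0.19) with its near-identical copy Pgk1-rs7 (1.12, SE 0.19), each with adjusted p = 0.245. The lower genes were the elastic-fibre protein gene Mfap4 (-1.14, SE 0.16), Greb1 (-1.23, SE 0.18), Pramel13 (-1.54, SE 0.22), Zfp783 (-1.19, SE 0.18) and the interferon-induced Oasl2 (-0.90, SE 0.14), each with adjusted p = 0.245. Cd96, a receptor of T and NK cells, the urea transporter gene Slc14a1 and Nemp2 were not well above background on any silenced array, and were at least 1.22-fold, 1.01-fold and 1.57-fold lower there (adjusted p = 0.245). Under scaling to the spike-in probes the median mouse gene stood at -0.42, against -0.03 here, so changes are given relative to the 75th percentile.

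Interferon-stimulated genes had the smallest camera p of the 31 lists tested on the mouse arrays and were lower in all 3 silenced tumours (median -0.74, camera adjusted p = 1.84e-11, adjusted p = 0.273 with an estimated correlation). Of 23 measured members 22 lay below 0, and 16 fell when adjusted over the list alone, 0 over all genes. The antiviral gene Oas2 was at -1.28 (SE 0.24), Ifi44 at -0.90 (SE 0.16), the ubiquitin-like Isg15 at -0.83 (SE 0.15) and Oasl2 at -0.90 (SE 0.14). The hypoxia and glycolysis list was higher, as on the human arrays (median 0.78, camera adjusted p = 1.02e-09, adjusted p = 0.297 with an estimated correlation). Human RNA on its mouse probes is not excluded. Of 20 measured members 20 lay above 0, and 14 passed when adjusted over the list alone. The vasodilator peptide gene Adm was at 1.82 (SE 0.42), Bnip3 at 1.47 (SE 0.26), Pgk1 at 1.11 (SE 0.19) and Pdk1 at 0.83 (SE 0.17). Both lists were called in the same direction under each alternative fit to the scanner files, with each array left out and by fry (adjusted p = 0.0116 and adjusted p = 0.041). No member of a list called on the mouse arrays passed over all genes.

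**Figure D3:**
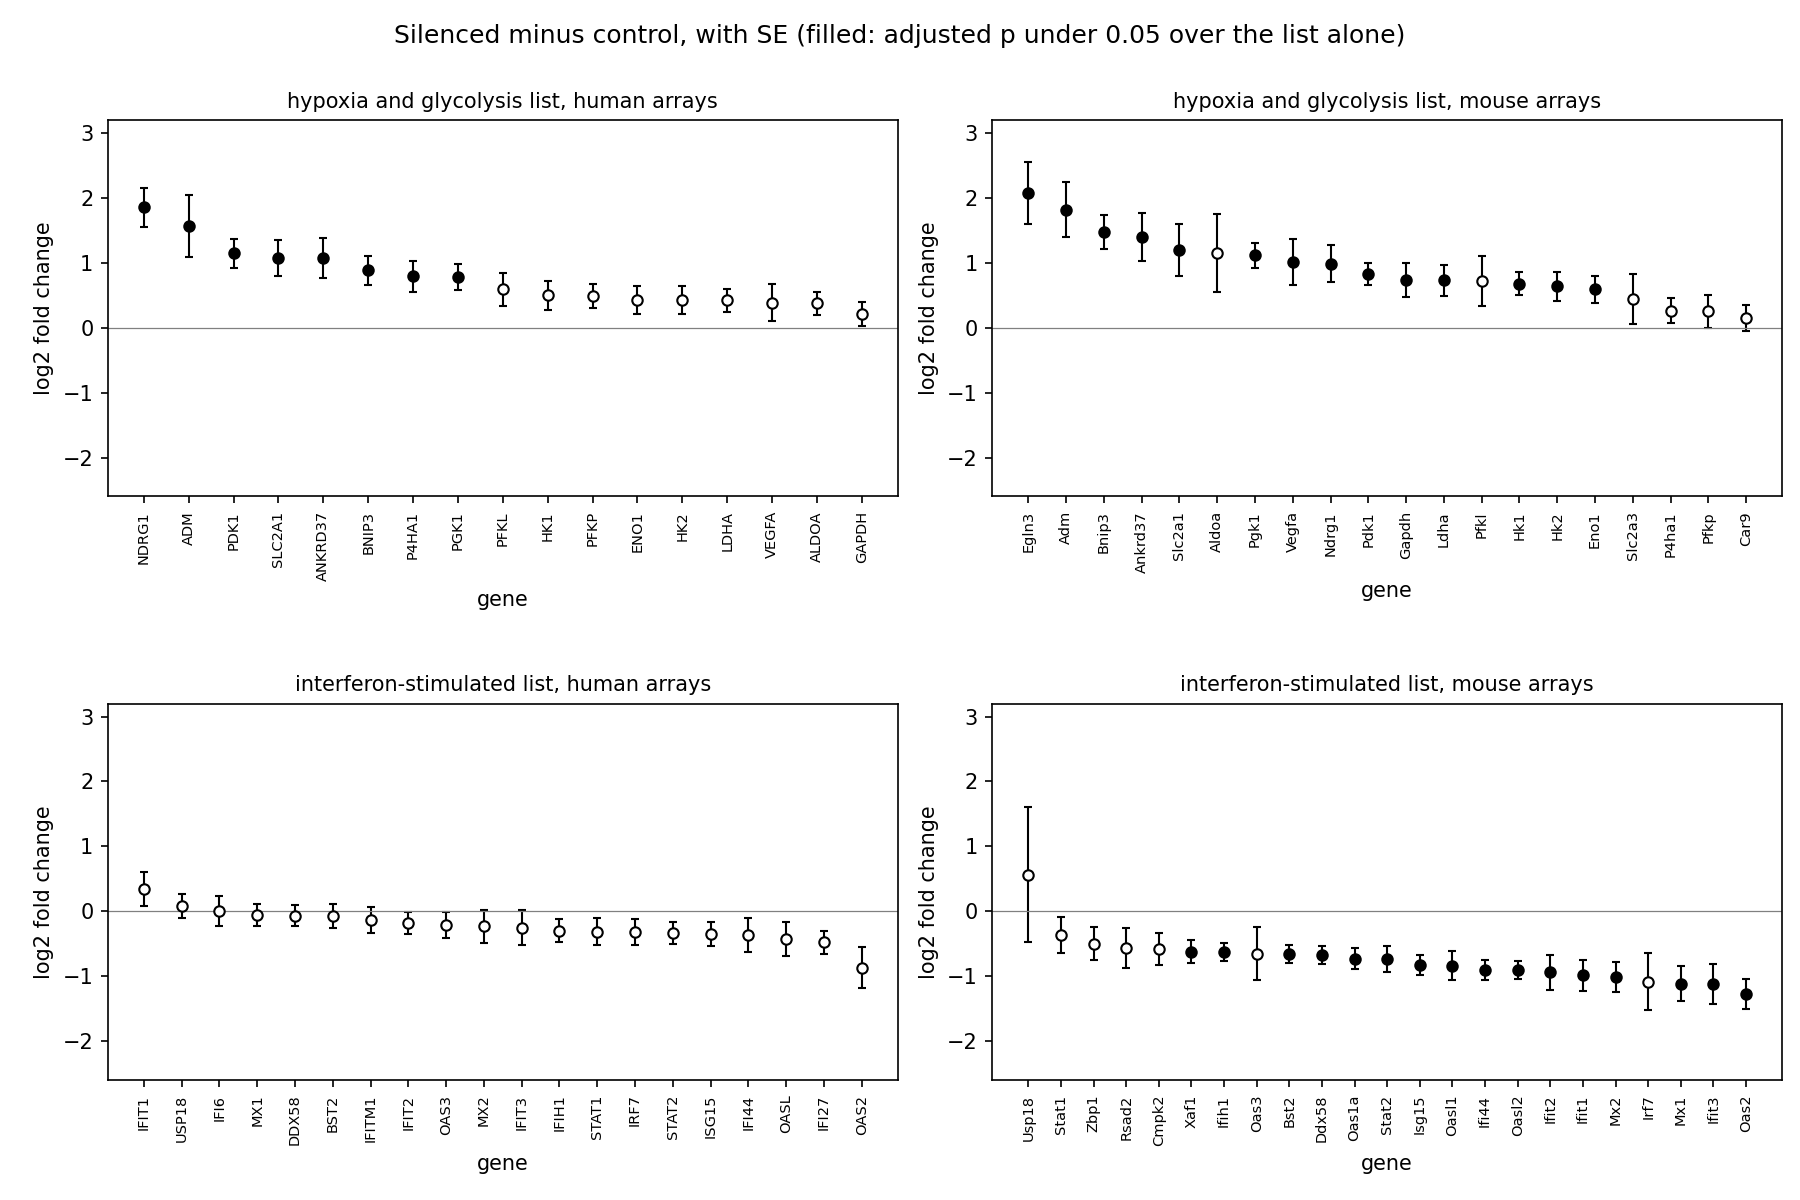
Log2 fold change, silenced minus control (vertical axis), of each measured member (horizontal axis) of the hypoxia and glycolysis and the interferon-stimulated lists on human and mouse arrays; bars are SE and filled points pass over the list alone. All 17 human and 20 mouse hypoxia members lie above 0, and 17 of 20 human and 22 of 23 mouse interferon members lie below 0.

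Antigen presentation, complement, chemokine, dendritic cell, pan-macrophage and NK cell lists were lower in the silenced tumours on the mouse arrays. MHC class II presentation was lower (median -0.55, camera adjusted p = 0.000894, adjusted p = 0.273 with an estimated correlation). Of 9 measured members 9 lay below 0, and 0 passed when adjusted over the list alone. H2-Oa was at -0.68 (SE 0.20), H2-Eb1 at -0.55 (SE 0.18) and H2-Aa at -0.74 (SE 0.27). The chemokine list was lower (median -0.68, camera adjusted p = 0.00136, adjusted p = 0.273 with an estimated correlation), with 15 of 18 members below 0, of which 2, the monocyte attractants Ccl2 (-0.91, SE 0.22) and Ccl7 (-0.82, SE 0.20), fell over the list alone, and Cxcl12 stood at -1.28 (SE 0.43). Complement genes were lower (median -0.60, camera adjusted p = 0.00134, adjusted p = 0.321 with an estimated correlation). Of 14 measured members 12 lay below 0, and 4 passed when adjusted over the list alone: Cfb (-0.85, SE 0.16), C1ra (-0.72, SE 0.17), C2 (-0.67, SE 0.16) and the properdin gene Cfp (-0.61, SE 0.17). The dendritic cell list was lower (median -0.57, camera adjusted p = 0.0032, adjusted p = 0.273 with an estimated correlation). Of 11 measured members 11 lay below 0, and 4 passed when adjusted over the list alone: Bst2 (-0.66, SE 0.14), Batf3 (-0.57, SE 0.14), Flt3 (-0.90, SE 0.27) and Irf8 (-0.49, SE 0.15). Bst2 is also induced by interferon. Pan-macrophage markers were lower (median -0.34, camera adjusted p = 0.00134, adjusted p = 0.501 with an estimated correlation). Of 20 measured members 19 lay below 0, and 0 passed when adjusted over the list alone. The Fc receptor gene Fcgr1 was at -0.66 (SE 0.16) and the growth factor receptor gene Csf1r at -0.56 (SE 0.16). MHC class I presentation was lower (median -0.38, camera adjusted p = 0.00664, adjusted p = 0.551 with an estimated correlation). Of 12 measured members 11 lay below 0, and 0 passed when adjusted over the list alone. Tapbp was at -0.62 (SE 0.16) and Tap1 at -0.59 (SE 0.17). The NK cell list was lower (median -0.74, camera adjusted p = 0.0258, adjusted p = 0.551 with an estimated correlation). Of 9 measured members 7 lay below 0, and 0 passed when adjusted over the list alone. Granzyme Gzmb was at -1.03 (SE 0.34) and the receptor gene Klrd1 at -0.89 (SE 0.31). Within row 1 of the slide the pan-macrophage list had an adjusted p = 0.0641. Without control 1 the adjusted p was 0.112 for MHC class I and 0.254 for NK cells on the mouse arrays. Without silenced 2 it was 0.067 and 0.0714, and without silenced 3 it was 0.115 for NK cells. The NK cell list was also lost with normexp (0.1004), the filter on all 6 arrays (0.111), array weights (0.0508) and the turned table (0.0971).

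The balance of M1 and M2 macrophage genes was examined because RNASET2 has been studied for its action on tumour macrophages. The M1 list was lower (median -0.46, camera adjusted p = 0.00764, adjusted p = 0.501 with an estimated correlation). Of 19 measured members 18 lay below 0, and 0 passed when adjusted over the list alone. Cd80, a costimulatory ligand, was at -0.78 (SE 0.19) and the chemokine gene Cxcl10 at -0.96 (SE 0.35). The nitric oxide synthase gene Nos2, a member of the same list, was at 0.84 (SE 0.36, adjusted p = 0.288). The M2 list was not called (median -0.09, camera adjusted p = 0.766), with 13 of 21 members below 0. The arginase gene Arg1 was at 1.05 (SE 0.46, adjusted p = 0.29) and the mannose receptor gene Mrc1 at -0.62 (SE 0.40, adjusted p = 0.415), which turned to 0.22 within row 1 of the slide. The general macrophage markers Adgre1 and Cd68 were at -0.28 (SE 0.21, adjusted p = 0.471) and -0.18 (SE 0.47, adjusted p = 0.843). Cd68 turned to 0.40 within row 1, to 0.09 without control 3 and to 0.25 without silenced 1. The mean of the M1 list minus that of the M2 list was 0.17 ± 0.59 (SD, n = 3) in control and -0.17 ± 0.09 in silenced tumours, a difference of -0.34 that the exact permutation test did not separate from chance (two-sided p = 0.5, smallest possible 0.1). Without control 1 this difference was -0.04. The M1 call was lost without control 1 (adjusted p = 0.0983) and without silenced 3 (adjusted p = 0.0527).

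Matrix, fibroblast and metabolic lists also shifted on the mouse arrays. Fibrillar collagen and matrix genes were lower (median -0.53, camera adjusted p = 0.00201, adjusted p = 0.544 with an estimated correlation). Of 20 measured members 17 lay below 0, and 2 passed when adjusted over the list alone: Fn1 (-1.08, SE 0.19) and Col11a1 (-1.13, SE 0.22), while Vcan and Loxl2 stood at 0.53 (SE 0.18) and 0.54 (SE 0.18). Fibroblast markers were lower (median -0.49, camera adjusted p = 0.0237, adjusted p = 0.501 with an estimated correlation). Of 16 measured members 14 lay below 0, and 0 passed when adjusted over the list alone. Fap, a protease of activated fibroblasts, was at -1.26 (SE 0.42) and Pi16 at -1.17 (SE 0.41), and S100a4 was at 0.53 (SE 0.18). Lysosomal genes were lower (median -0.27, camera adjusted p = 0.0258, adjusted p = 0.551 with an estimated correlation). Of 22 measured members 18 lay below 0, and 0 passed when adjusted over the list alone. The sialidase gene Neu1 was at -0.35 (SE 0.14). Ribosomal protein genes were higher relative to other genes (median 0.33, camera adjusted p = 7.99e-05, adjusted p = 0.501 with an estimated correlation). Of 24 measured members 19 lay above 0, and 0 passed when adjusted over the list alone. Rps2 was at 0.81 (SE 0.23). Oxidative phosphorylation was higher relative to other genes (median 0.27, camera adjusted p = 0.00201, adjusted p = 0.593 with an estimated correlation). Of 22 measured members 21 lay above 0, and 0 passed when adjusted over the list alone. Ndufa4 was at 0.61 (SE 0.18). Oxidative phosphorylation and the skeletal muscle list were both highest in silenced 3 (0.67 and 5.19 from the control mean) and lowest in control 3 (-0.11 and -5.40). The mean of the ribosomal proteins list turned from 0.31 to -0.04 under quantile normalization, where camera no longer called it (adjusted p = 0.842), nor in the turned table (adjusted p = 0.527). Within row 1 the adjusted p was 0.0758 for the collagen, 0.937 for the fibroblast and 0.732 for the lysosomal list. The fibroblast call was also lost without control 2 (0.173) or silenced 3 (0.159). The lysosomal call was lost without control 3 (0.167), silenced 1 (0.243) or silenced 3 (0.0547), and oxidative phosphorylation without silenced 3 (0.262). On the mouse arrays oxidative phosphorylation was also lost with normexp (0.208) and no filter (0.0793), and the lysosome and endocytosis list with the mean of probes (0.0507).

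Lists of markers of adipose tissue, muscle and neutrophils were also called higher on the mouse arrays. The adipocyte list was higher in silenced tumours (median 1.70, camera adjusted p = 0.00121, adjusted p = 0.501 with an estimated correlation). Of 11 measured members 11 lay above 0, and 0 passed when adjusted over the list alone. Lipoprotein lipase Lpl was at 0.89 (SE 0.29) and the lipid droplet gene Plin4 at 2.32 (SE 0.77). Its mean lay 3.08 above the control mean in silenced 1, 1.23 in silenced 2 and 0.61 in silenced 3, and control 2 stood at 1.02. The adipocyte list was called in all 20 alternatives with the preset correlation, each left-out array among them, and not by fry. Skeletal muscle genes were higher (median 3.15, camera adjusted p = 0.00353, adjusted p = 0.608 with an estimated correlation). Of 16 measured members 16 lay above 0, and 0 passed when adjusted over the list alone. Myoglobin Mb was at 3.50 (SE 2.45) and the troponin gene Tnnt3 at 3.73 (SE 2.71). Control 3 lay at -5.40 and silenced 3 at 5.19 for this list, and without control 3 its adjusted p was 0.457, without silenced 3 it was 0.0996, and within row 1 it was 0.527. The skeletal muscle list was also lost with no filter (0.0599) and the filter on all 6 arrays (0.0782). Of the skin and keratinocyte list 4 genes were measured, too few for the test, and their mean lay 5.80 above the control mean in silenced 1 and 0.41 and 0.46 in silenced 2 and 3. Neutrophil genes were higher (median 0.56, camera adjusted p = 0.0128, adjusted p = 0.359 with an estimated correlation). Of 8 measured members 8 lay above 0, and 0 passed when adjusted over the list alone. Lcn2, which epithelia also make, was at 0.68 (SE 0.21) and myeloperoxidase Mpo at 0.53 (SE 0.21). On the mouse arrays the neutrophil call was lost without silenced 1 (adjusted p = 0.104) and without silenced 2 (adjusted p = 0.0512). It was also lost with no filter (0.41) and array weights (0.0531). The receptor gene Csf3r (0.33, SE 0.14) changed sign under quantile normalization.

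Across 9552 genes with the same symbol on both designs, the log2 fold changes of the human and mouse arrays had a Pearson r of 0.19 and a Spearman rho of 0.12, a description across genes, which are not independent replicates. An unadjusted p under 0.05 on both designs was found for 227 of them, against 151.3 expected from independent lists, and 188 (82.8%) had the same sign, 75 higher and 113 lower. Among aligned probe pairs of the same symbol the correlation was 0.58 over the 258 pairs with at least 90% sequence identity and 0.04 over the 263 pairs with less.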

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

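The tests of the value table columns and of RNASET2 in the scanner files, of the slide row and of the immune against the vascular lists were chosen after the results were seen; the other tests in this part were written beforehand.

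RNASET2 was higher, not lower, in the columns named silenced of the human value table that the authors deposited beside the scanner files, a table outside the main measurement. It stood at 13.35 ± 0.05 (SD, n = 3) in columns named silenced and 10.92 ± 0.12 in columns named control, a log2 difference of 2.44. Every one of the 12 columns of both tables followed the scanner file of the opposite group with the same number, with correlations of between-array differences from 0.937 to 0.989, against -0.646 to 0.136 with its own. An exchange of the columns of the groups in the value tables is consistent with this. An exchange of the human scanner files is argued against by RNASET2, which was at -2.41 in them. For the mouse scanner files, each of the 6 human arrays correlated better over same-symbol genes with the mouse array of its own label than with that of the opposite group (mean difference 0.332, range 0.133 to 0.709), and best of all 6 with its own, which argues against an exchange of mouse files alone. The mouse arrays hold no check by the targeted gene, so the mouse directions rest on the labels shared by both designs and on this match.

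Same-symbol genes moved together on the human and mouse designs (r = 0.19). RNA of one species binding probes of the other is consistent with the aligned probe pairs, where r was higher by 0.538 (95% bootstrap interval 0.33 to 0.744) at or above 90% identity than below it. The interval counts genes as independent, and the test does not tell whether human RNA bound mouse probes or mouse RNA bound human probes. Without the members of the hypoxia list r was 0.188 (interval 0.155 to 0.221), over 9535 of the 9552 genes. The written members alone thus do not carry the correlation. So few genes were removed that this says nothing of hypoxia genes outside the list. What lies behind the correlation of 0.189 over the 8921 genes whose probes did not align stays open, and a response shared by both species was not tested.

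The interferon, antigen presentation, chemokine, complement, dendritic cell, pan-macrophage, M1 and NK cell lists were lower on the mouse arrays of silenced tumours. None of these 9 lists was called with an estimated correlation (adjusted p between 0.273 and 0.551). With the slide row as a block 8 of these 9 lists were still called lower, but control 1 is the only control in the row of the silenced tumours, so position on the slide stays open. Dilution of leukocyte RNA by other tissue may contribute. Adipocyte and skeletal muscle lists were higher in silenced tumours (mean 1.64 and 3.02), the muscle list not without control 3, and fibroblast markers were lower (mean -0.51). The 9 immune lists were chosen because they were called lower. The mean of the 128 genes of these lists shifted by -0.50 and that of 31 endothelial and pericyte genes by -0.03. The difference of -0.472 had a 95% interval over arrays of -1.003 to 0.06, so that dilution and a change within the immune lists cannot be told apart with 6 arrays. Array by array the difference lay no higher than 0.097 in silenced and no lower than 0.167 in control tumours. Of the other leukocyte lists, neutrophil genes were higher (median 0.56, camera adjusted p = 0.0128, lost in 4 of 20 alternatives with the preset correlation). The neutrophil list was not called with an estimated correlation (adjusted p = 0.359) or by fry (adjusted p = 0.131). T cell genes were not called (median -0.02). The silencing itself, the design's biological difference, stays open, and so does the clone, since the labels give 3 different clones for each group.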

How the results depend on the processing

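The value table with its sign turned and the mouse arrays without probes aligned to human probes were chosen after the data were seen; the other alternatives were fixed beforehand. Where a change is given, the cause was not tested, unless the alternative itself shows it. Every change of direction is given below, called or not, with the direction of a list taken from camera. A turn of a list mean alone, as for mouse ribosomal proteins with quantile normalization, is not repeated there. An earlier version of the labelling script left changes of results called in neither setting out and only counted them, and was corrected after the values were seen.

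RNASET2 on human arrays kept its direction in all scanner-file settings and lost its call with median centring (-2.24), spike-in scaling (-2.35), no filter (-2.41), the mean of its probes (-1.74), the slide row block (-2.57) and the replicate block (-2.41). The adjusted p there lay between 0.0524 and 0.254. Leaving out single arrays gave -2.47 to -2.32, and the table as named 2.44 (adjusted p = 0.00117). Human genes called went from 1 to 0 with median centring, spike-ins, no filter and the mean of probes, and to 0 with any array left out. They numbered 11 with array weights (2 higher, 9 lower), 10 with the slide row block (10 lower, RNASET2 not among them) and 1, higher, in the table as named. Mouse genes called went from 2 to 0 with normexp, no filter, the intensity trend, the slide row block, the table as named or turned, and any array left out. They also went to 0 with the filter on all arrays, which leaves out the probes behind both calls and so does not test them. Mouse genes called numbered 1 (higher) with quantile, median and spike-in scaling. AW555355 on mouse arrays stood at 0.012 with normexp, and Foxa2 on mouse arrays at -0.67 in the table as named.

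The labels do not say that a replicate number marks a shared batch. Deviations of same-numbered tumours correlated at 0.29, 0.07 and -0.01 on human and 0.18, 0.12 and -0.30 on mouse arrays. With 3 values per design this does not settle whether the numbers pair the samples. With the replicate block 0 human and 0 mouse genes were called, and 9 and 19 lists. The M1 minus M2 difference is -0.34 with or without this block, since balanced pairs leave a mean difference unchanged. The block ended the call of the human mesenchymal and EMT list (0.0646) and gave one to the mouse erythroid list (0.0182).

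Human lists called numbered 10, 6 higher and 4 lower. They numbered 3, all higher, with the slide row block, 0 with an estimated correlation, 0 with fry, 7 in the table as named and 5 to 12 on leaving out single arrays. The split was 7 higher to 1 lower with spike-ins, 6 to 2 with the percentile over detected probes, 10 to 4 with no filter, 7 to 2 with the mean of probes and 8 to 1 with array weights. Mouse lists called numbered 18, 6 higher and 12 lower (4 and 14 with no filter), against 0 with an estimated correlation, 7 with fry (2 higher, 5 lower), 16 in the table as named and 12 to 18 on leaving out single arrays. Fry called the interferon-stimulated, dendritic, MHC class II, chemokine, hypoxia and complement lists, and the epithelial orthologues. Without the 1223 kept mouse probes aligned to human probes, the same 18 mouse lists were called. The alignment was to human probe sequences and not to human transcripts. The probes left in can therefore still bind human RNA, and cross-species binding stays open.

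In the table as named the lists called from the scanner files all had the opposite sign, 10 of 10 on human and 18 of 18 on mouse arrays. On human arrays their adjusted p there was, for mesenchymal and EMT 0.0624, fibrillar collagen and matrix 0.0144, cell cycle 5.29e-06, interferon-stimulated 0.00369, hypoxia and glycolysis 1.38e-11, oestrogen response 0.0144, stress and immediate early 0.0578, metallothioneins 0.000141, oxidative phosphorylation 0.0603 and host leukocyte orthologues 0.103. On mouse arrays it was, for pan-macrophage 3.22e-05, M1 macrophage 0.00701, neutrophil 0.0306, dendritic cell 0.000797, MHC class II presentation 0.000105, MHC class I presentation 5.55e-05, NK cell 0.0971, fibroblast 0.00701, fibrillar collagen and matrix 0.000273, interferon-stimulated 2.12e-11, chemokines 0.000529, hypoxia and glycolysis 2.24e-09, skeletal muscle 0.00438, adipocyte 0.00106, ribosomal proteins 0.527, oxidative phosphorylation 0.0191, lysosome and endocytosis 0.000797 and complement 0.000273. Lists not called from the scanner files that had the opposite sign there were, on human arrays, RNase family 0.468, epithelial and ovarian carcinoma 0.163, basement membrane 0.403, integrins and cell adhesion 0.163, matrix proteases and inhibitors 0.146, cytoskeleton and contractility 0.0761, MHC class I presentation 0.0158, chemokines and myeloid factors 0.337, unfolded protein response 0.104, cholesterol biosynthesis 0.409, TGF-beta targets 0.149, Wnt targets 0.2004, ribosomal proteins 0.0603, host endothelial and fibroblast orthologues 0.341 and host muscle and skin orthologues 0.21. On mouse arrays they were M2 macrophage 0.619, T cell 0.902, B cell and plasma cell 0.485, endothelial 0.711, basement membrane 0.105, matrix proteases and inhibitors 0.248, angiogenic factors 0.802, cell cycle 0.911, erythroid 0.181, nerve and Schwann cell 0.816, epithelial carcinoma orthologues 0.0823 and stress and immediate early 0.227.

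Lists on human arrays whose direction differed in other settings are given with their adjusted p there. With quantile normalization these were p53 targets and apoptosis (0.838), NF-kB and inflammatory (0.717), lysosome and endocytosis (0.393) and autophagy (0.717). With median centring these were NF-kB and inflammatory (0.654) and angiogenic factors (0.912). With spike-in scaling these were NF-kB and inflammatory (0.985). With no filter these were cytoskeleton and contractility (0.945). With the filter on all 6 arrays these were NF-kB and inflammatory (0.813) and angiogenic factors (0.71). With the mean of a gene's probes these were NF-kB and inflammatory (0.965). With the intensity trend these were NF-kB and inflammatory (0.987). With array weights these were epithelial and ovarian carcinoma (0.938), p53 targets and apoptosis (0.942), chemokines and myeloid factors (0.945), angiogenic factors (0.828), lysosome and endocytosis (0.97) and autophagy (0.942). With the slide row block these were integrins and cell adhesion (0.74), cytoskeleton and contractility (0.812), p53 targets and apoptosis (0.672), NF-kB and inflammatory (0.74), cholesterol biosynthesis (0.436) and ribosomal proteins (0.672). With the replicate block these were NF-kB and inflammatory (0.769). With the turned table these were p53 targets and apoptosis (0.834), NF-kB and inflammatory (0.471), angiogenic factors (0.766), lysosome and endocytosis (0.337) and autophagy (0.615). On leaving out single arrays they were, with the range over all 6, p53 targets and apoptosis (0.369 to 0.939), NF-kB and inflammatory (0.0095 to 0.954), integrins and cell adhesion (0.112 to 0.977), host muscle and skin orthologues (0.0298 to 0.916), cytoskeleton and contractility (0.238 to 0.977), chemokines and myeloid factors (0.165 to 0.769), angiogenic factors (0.382 to 0.968), lysosome and endocytosis (0.654 to 0.957) and autophagy (0.471 to 0.836).

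Lists on mouse arrays whose direction differed in other settings follow in the same form. With normexp these were B cell and plasma cell (0.964), pericyte and smooth muscle (0.754), angiogenic factors (0.959) and nerve and Schwann cell (0.963). With quantile normalization these were pericyte and smooth muscle (0.842). With spike-in scaling these were M2 macrophage (0.912). With no filter these were T cell (0.519), pericyte and smooth muscle (0.456) and angiogenic factors (0.46). With the mean of a gene's probes these were pericyte and smooth muscle (0.979). With the slide row block these were M2 macrophage (0.256), T cell (0.00889), endothelial (0.336), pericyte and smooth muscle (0.937), matrix proteases and inhibitors (0.373), cell cycle (0.947) and nerve and Schwann cell (0.209). With the turned table these were pericyte and smooth muscle (0.838). With aligned probes left out these were T cell (0.874). On leaving out single arrays they were, with the range over all 6, M2 macrophage (0.312 to 0.957), T cell (0.117 to 0.995), pericyte and smooth muscle (0.639 to 0.944), nerve and Schwann cell (0.254 to 0.943), endothelial (0.191 to 0.955), angiogenic factors (0.234 to 0.868), matrix proteases and inhibitors (0.0765 to 0.979) and cell cycle (0.104 to 0.972).

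Many signs of the named genes could not turn in settings other than the table as named. The intensity trend and the replicate block leave the fold changes as they were. Genes picked for no overlap keep their sign without any single array. Counts over these settings are therefore no measure of how stable the directions are. The named genes had the opposite sign in the table as named for 52 of 52 on human and 87 of 88 on mouse arrays, and in other settings for 3 of 1037 and 8 of 1785 values. Their log2 differences in the table as named on human arrays, beside RNASET2, were LEMD1 -1.94, DHRS3 -2.42, DSCAML1 -1.12, ALDH1A1 -2.77, NDRG1 -1.78, RRM2 -0.98, TCF4 1.37, GPR18 0.54, HLA-DRB1 1.32, BHLHE22 0.69, HLA-DQB1 1.25, DAPP1 0.43, S100A2 1.52, EPCAM 0.36, VIM -0.27, MKI67 -0.044, PDK1 -1.03, PGK1 -0.69, BNIP3 -0.79, MCM2 -0.49, TOP2A -0.55, TYMS -0.35, MT1L -0.56, MT1B -0.51, MT1E -0.43, MT1H -0.33, SDHB -0.21, UQCRFS1 -0.32, ATP5A1 -0.16, FOS -1.24, FOSB -0.60, EGR2 -0.32, DUSP1 -0.37, COL1A2 1.24, FN1 0.57, COL1A1 1.04, ELN 0.71, IFI27 0.31, STAT2 0.43, ISG15 0.44, CA12 -1.47, STC2 -0.55, TFF3 -0.82, SIAH2 -0.40, CD74 0.96, C1QB 0.87, ITGAM 0.25, EMR1 0.054, CDH2 0.88, ZEB2 0.89 and TAGLN 0.98. On mouse arrays they were Foxa2 -0.67, Vldlr -1.10, Fbll1 -0.56, Klf5 -0.97, Cracd -0.72, Pgk1-rs7 -0.95, Rbpj -0.85, Pgk1 -0.95, Cd96 0.24, Slc14a1 0.25, Mfap4 1.23, Pramel13 0.58, Greb1 0.96, Oasl2 0.85, Nemp2 0.24, Zfp783 0.61, Rnaset2a 0.52, Adgre1 0.32, Cd68 0.10, Nos2 -0.65, Arg1 -0.51, Mrc1 0.60, Ifi44 0.85, Isg15 0.97, Oas2 1.16, Bnip3 -1.34, Pdk1 -0.29, Adm -1.58, Rps2 -0.40, Rps24 -0.11, Rps18 -0.16, H2-Oa 0.19, H2-Eb1 0.94, H2-Ab1 0.89, H2-Aa 0.76, Lpl -0.80, Plin4 -1.51, Cidec -1.47, Fcgr1 0.56, Csf1r 0.83, Aif1 0.70, Laptm5 0.63, Cfb 0.93, C1ra 0.81, C2 0.80, Cfp 0.63, Ccl2 0.96, Ccl7 0.77, Ccl12 0.79, Cxcl12 1.11, Fn1 1.46, Col11a1 0.996, Vcan -0.46, Loxl2 -0.48, Ndufa4 -0.46, Ndufb8 -0.31, Uqcrc1 -0.48, Bst2 0.68, Batf3 0.40, Flt3 0.32, Irf8 0.58, Mb -1.99, Tnni2 -2.39, Pvalb -2.07, Tnnt3 -2.45, Tapbp 0.69, Tap1 0.47, H2-T23 0.61, H2-D1 0.56, Cd80 0.53, Fpr2 0.40, Cxcl10 0.95, Lcn2 -0.47, Mpo -0.19, Elane -0.48, Fap 1.39, Pi16 1.31, S100a4 -0.11, Fbln1 1.37, Gzmb 0.64, Klrd1 0.28, Ncr1 0.23, Gzma 0.82, Neu1 0.34, Lipa 0.39, Psap 0.66 and Hexa 0.63.

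Among results not called, the list NF-kB and inflammatory on human arrays had an adjusted p between 0.0095 (higher, without silenced 1) and 0.954 on leaving out arrays, and turned lower at 0.0225 without silenced 2. The list T cell on mouse arrays turned lower at 0.00889 with the slide row block. Others gained a call in their own direction. On mouse arrays these were B cell and plasma cell with the slide row block (0.0362), erythroid with the replicate block (0.0182) and without control 2 (0.00574), epithelial carcinoma orthologues with spike-ins (0.0436), matrix proteases and inhibitors with no filter (0.0437), and basement membrane with normexp (0.0102), no filter (0.00676) and without control 1 (0.0227) or silenced 2 (0.0316). On human arrays ribosomal proteins gained one with normexp (0.0131), median centring (0.0184), no filter (0.00691), the mean of probes (0.015), array weights (0.00419) and without control 1 (0.00301) or silenced 2 (0.0198). Cholesterol biosynthesis did so with spike-ins (0.0499), no filter (0.0155), array weights (0.0033) and without control 1 (0.00157). MHC class I presentation on human arrays did so with quantile normalization (0.0253), the turned table (0.0158) and without control 2 (0.0298), and host muscle and skin orthologues with array weights (0.031) and without control 2 (0.0298). With no filter TGF-beta targets (0.00807), Wnt targets (0.0283) and host endothelial and fibroblast orthologues (0.0374) were called. MKI67 on human arrays stood at -0.30 with the slide row block and between -0.17 and 0.28 on leaving out arrays. On the mouse arrays Csf3r stood at -0.093 with quantile normalization, -0.062 with spike-ins, which shift all mouse genes down alike, and -0.083 in the turned table. Cd68 on mouse arrays stood at 0.40 with the slide row block and between -0.56 and 0.25 on leaving out arrays, and Mrc1 on mouse arrays at 0.22 with the slide row block.

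M1 minus M2 ranged from -0.63 to -0.04 on leaving out arrays and was 0.25 in the table as named. The share of probes above background differed by 0.24 to 2.84 points on human and -7.07 to -4.76 on mouse arrays. The array signal against spike-in controls on human arrays differed by -0.10 to 0.18, and by -0.046 with the median, and that on mouse arrays by -0.57 to -0.20. The correlation between designs ranged from 0.155 to 0.245. Dim probes limit the folds of Foxa2, FOXA2, Cd96, Slc14a1, Nemp2, Ncr1 and AW555355 to bounds.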

Other observations

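The tests of other splits in this part were written before they were run.

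Several host cell lists on the mouse arrays showed no call. Endothelial genes had a median of -0.13 (camera adjusted p = 0.524), pericyte and smooth muscle genes 0.01 (0.845), angiogenic factors 0.09 (0.785), T cell genes -0.02 (0.78), B and plasma cell genes -0.11 (0.445) and nerve and Schwann cell genes -0.16 (0.766). Cell cycle genes, higher on the human arrays, had a median of -0.16 on the mouse arrays (0.749). The 10 measured mouse orthologues of epithelial carcinoma markers had a median of 0.37 (0.135), with 9 above 0, and the erythroid list 0.43 (0.0992). With the slide row as a block the T cell and the B cell and plasma cell lists were called lower. That comparison rests on control 1 alone, where these lists lay 1.06 and 0.38 above the control mean. With the replicate block the erythroid list was called higher (0.0182). On the human arrays ribosomal protein genes had a median of 0.11 (0.0727), MHC class I genes -0.11 (0.199), cholesterol biosynthesis genes 0.10 (0.127), p53 targets 0.06 (0.705) and the epithelial and ovarian carcinoma list -0.04 (0.501). The human NF-kB list had a median of -0.08 while camera ranked it higher (0.952). A p that misses the threshold does not show that these lists were alike in the groups.

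Among the mouse lists too small to test, Ccl21a, a chemokine of lymphatic vessels and lymph nodes, had a log2 fold change of 4.23 (adjusted p = 0.245 over all genes), and it was named after its value was seen. Pdpn, the other measured member of its list, was at -0.30 (adjusted p = 0.45).

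There are 10 ways to split the 6 arrays of a design into 3 and 3, too few for a share under 0.05. On human arrays the real split called 1 gene and the highest other 0, so that 1 split gave as many. An unadjusted p under 0.05 was found for 1993 human genes in the real split, 1938 with control 1, control 2 and silenced 1 against the others, and 1739 with control 1, silenced 1 and silenced 3 against the others. For lists the real split called 10 and the highest other 11, and 3 splits gave as many. The split with 11 set control 1, silenced 1 and silenced 2, which share row 1, against the others, and with the row as a block the real comparison called 3 human lists. On mouse arrays the real split called 2 genes and the highest other 1 (1 split as many), and 18 lists against 13 (1 split as many). The mouse split with 13 lists set control 1, silenced 1 and silenced 3, also in row 1, against the others, and had 2388 genes with an unadjusted p under 0.05. With the row as a block the real comparison called 15 mouse lists. They included the T cell and the B cell and plasma cell lists, which the main fit did not call. The pan-macrophage, collagen, fibroblast, skeletal muscle and lysosomal lists, called in the main fit, were not among them.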
